A study of Mus musculus with 120 samples.

How the data were processed

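Single cells from the endolymphatic sac of the mouse inner ear at embryonic day 14.5 were measured by Smart-seq2, a full-length single-cell RNA sequencing protocol, in wild-type animals and in animals carrying the Sox9Y440X allele over a wild-type copy (Sox9Y440X/+). The allele is named for a stop codon at residue 440 of the protein. The authors deposited their values as FPKM, fragments scaled to transcript length and to the fragments sequenced in the cell, in 1 table of 48555 gene entries and 120 cells. The submitters' processing notes name HISAT2, SAMtools 0.1.18, Cufflinks and HTSeq and the mouse genome build mm10, without roles or order. Their settings, the annotation and any filter on cells are not given in the sources used here. No value column without a matching sample was left over.

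FPKM values carry no read counts, so the depth of each cell is unknown and no counting error of a single expression value can be given. The lowest values above 0 reached 8e-318, too low to stand for reads, so a gene was called detected at an FPKM of at least 1. Exact zeros can be failed estimates: Gapdh was listed at 0 in 2 of the 115 cells used and Eef2 in 5, while Actb and Eef1a1 were above 0 in all of them. The 13 mitochondrially encoded genes were listed at 0 in every cell and give no result here. The number of genes per cell in the labels equalled the number of entries above 0 in all 120 cells. The summed FPKM per cell ranged from 192089 to 4444520 with a median of 462576, and the symbol AC155839.1 exceeded an FPKM of 100000 in 2 cells.

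Entries with the same gene symbol were summed, which joined 345 entries into 161 symbols and left 48371 symbols. Of the gene identifiers, 99.3% were found in GENCODE release M21 on GRCm38, the same assembly as mm10, which gave the coordinates. Of 454 listed genes, 448 were matched, 2 of them by an older symbol (Lect1 for Cnmd, 3110079O15Rik for Snorc). Cells with fewer than 1000 genes per their label were left out. This removed 1 wild-type and 4 Sox9Y440X/+ cells and left 57 and 58. No 2 cells had near-identical values, the highest correlation between cells being 0.698.

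The labels tie no cell to an animal, litter or plate. Each genotype was therefore treated as 1 sample, cells were not used as replicates, and no test or p-value was computed. For each gene the mean of log2(FPKM + 1) over cells was compared as Sox9Y440X/+ minus wild type. This difference is on the log2(FPKM + 1) scale, with a pseudocount of 1, and understates differences of low genes. SDs are over cells. Shares of cells are given with exact Clopper-Pearson 95% intervals, which cover counting error only and leave out differences between animals.

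Cells were clustered by Ward linkage on 15 principal components of the 1500 most variable genes of log2(FPKM + 1) among those detected in at least 5 cells, and the tree was divided into 8 clusters. Clusters were named from 12 marker lists by the list with the highest mean level, with at least 3 markers detected in at least 50% of the cluster's cells. Clusters led by mesenchyme or chondrocyte markers were joined as mesenchyme-like, and those led by epithelium or ionocyte markers as epithelium-like. An epithelium-like cluster with at least 8 ionocyte markers detected in at least 50% of its cells was called ionocyte-like. Doublets were not removed with a caller. Instead, cells with at least 5 epithelium and at least 5 mesenchyme markers were counted.

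There were 21 programme lists, fixed before the data were examined, as were the markers, the rule for named genes and most of the other settings tried. For each list the median of its members' differences was placed among 10000 random lists of the same size, each gene drawn from 100 genes of similar mean expression. These percentiles describe the cells measured and are not p-values. Genes named by rule were Sox9, Sox10, Sox8, Foxi1 and Slc26a4. To these came the 12 largest positive and 12 largest negative differences, over all cells and within epithelium-like cells. They were taken among genes detected in at least 25% of the cells of 1 genotype whose sign held in odd-numbered cells, in even-numbered cells and after scaling to the same total. Symbols of the Gm-number, mt-, Rik, -ps, Rpl and Rps kinds were passed over. Of each list, 2 to 4 members were named by largest difference, or by highest expression where none differed by 1 log2 unit. Oc90 and Sox10 within single clusters, the sex-linked genes and the genes of mesenchyme-like cells were chosen after their values were seen.

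Other settings fixed before the data were examined were pseudocounts of 0.1 and 10, the log2 ratio of mean FPKM, scaling to the same total, all 120 cells, cells with at least 2000 genes, cells with 2500 to 5500 genes, odd-numbered or even-numbered cells alone, list members detected in at least 10% of cells, other detection limits, 5 or 12 clusters and 3000 variable genes. Wild-type cells without Xist and cells outside the ionocyte-like cluster were added after seeing the data. The procedure was tested on simulated data: wild-type epithelium-like cells were resampled into groups of the real sizes and 200 of 4623 genes were altered by a factor of 4. The right direction came back for 93.0% of the raised and 97.0% of the lowered genes. Of 20 lists of 19 altered genes in each direction, 100% lay outside the central 95% of random lists on the right side, and of 20 lists of unaltered genes 10.0% lay outside it. The genes were drawn at random from those detected in at least 25% of wild-type epithelium-like cells, and both groups came from the same cells. The simulation therefore does not cover lists expressed together in few cells, such as the ionocyte list, or different mixes of clusters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.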

Results

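The endolymphatic sac is a fluid-filled outpocketing of the inner ear whose epithelium includes ionocyte-type cells, which move acid and anions across it. SOX9 and SOX10 are related transcription factors of the SoxE group. Single-cell expression was measured in embryos of 1 age in 58 wild-type and 62 Sox9Y440X/+ cells. With cells of unknown animals there was 1 sample per genotype, so the values below have no replicate error. The median number of genes at an FPKM of at least 1 was 2822.5 in wild-type cells, with a range of 402 to 5429, and 3545.5 in Sox9Y440X/+ cells, with a range of 123 to 5645. The comparisons used 57 wild-type and 58 Sox9Y440X/+ cells with at least 1000 genes.

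The first comparison asked whether the sac samples of the 2 genotypes held the same cell types. Nearly all wild-type cells were epithelium-like, 56 of 57 (98.2%, 95% interval 90.6% to 99.96%), against 37 of 58 Sox9Y440X/+ cells (63.8%, 50.1% to 76.0%). Mesenchyme-like cells, named from collagen and other connective tissue markers, numbered 1 in wild type (1.75%, 0.0444% to 9.39%) and 21 in Sox9Y440X/+ (36.2%, 23.99% to 49.9%). The mesenchyme-like cells formed clusters 4 and 5, led by genes such as Col3a1, Col1a2 and Igfbp4. Epithelium markers were nearly absent from them: the median mesenchyme-like cell had 0 of 14 at an FPKM of at least 1 and the highest had 2. Among mesenchyme-like cells, 1 had no mesenchyme marker at that limit and rests on its cluster alone. No cell had at least 5 epithelium and at least 5 mesenchyme markers. Of the other marker lists, the endothelium median difference over all cells was 0.13 with 3 of 11 members detected in 10% of cells, and the pericyte median was 0.17 with 2 of 7. Both lay above the random lists, at percentiles 99.2 and 99.3, and mean endothelium marker levels were highest in cluster 5, at 1.26. The melanocyte median was 0.03 and the chondrocyte median 0.09, and those of macrophage, erythroid, neuron, glia and muscle markers were 0.00.

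**Figure D1:**
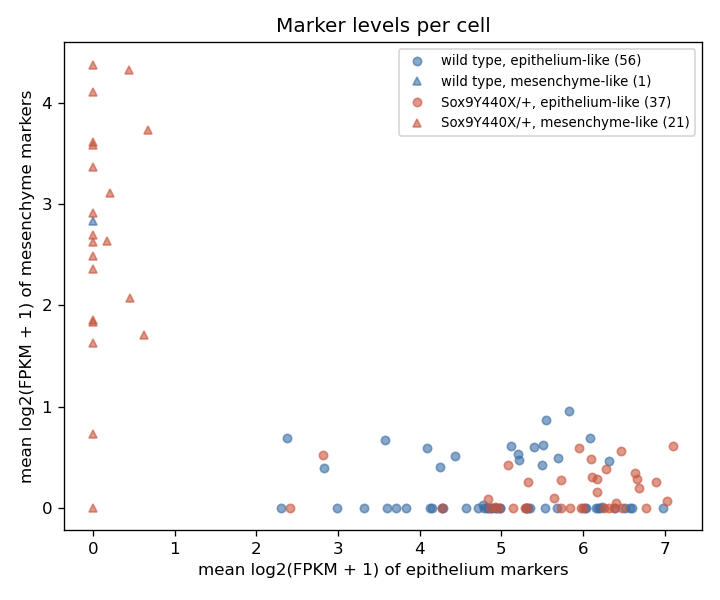
Each point is 1 cell, placed by the mean log2(FPKM + 1) of the epithelium markers (x axis) and of the mesenchyme markers (y axis), coloured by genotype and shaped by class. Of the 22 mesenchyme-like cells, 21 came from the Sox9Y440X/+ sample.

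Epithelium-like cells fell into 6 clusters with different leading genes. Cluster 1, with 8 wild-type and 5 Sox9Y440X/+ cells, was ionocyte-like and led by Atp6v1c2, Foxi1 and Slc26a4. Cluster 6, led by Spp1 and Oc90, held 22 wild-type and 6 Sox9Y440X/+ cells, and cluster 3, led by Aldh1a1, held 11 of each. Cluster 2, led by Fam132a and Aldh1a3, held 1 wild-type and 10 Sox9Y440X/+ cells, cluster 7 held 4 and 5, and cluster 8 held 10 wild-type cells and no other. The median number of genes per label was lowest in cluster 8, at 2057.5, followed by 2538 in cluster 7, and highest in cluster 3, at 5325. With 1 sample per genotype, clusters nearly of 1 genotype can reflect that sample, and the values within epithelium-like cells below compare different mixes of clusters, with cluster 6 the most frequent in wild type and clusters 2 and 3 in Sox9Y440X/+.

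The second comparison concerned the targeted gene. Sox9 (ENSMUSG00000000567.5, GRCm38 chromosome 11, 112782224 to 112787760) was higher in the cells that carry the mutant allele. In epithelium-like cells its mean FPKM was 4.11 in wild type and 16.6 in Sox9Y440X/+, and the difference of mean log2(FPKM + 1) was 2.01, from 1.57 (SD 1.52 over cells) to 3.58 (SD 1.40). Sox9 reached an FPKM of 1 in 29 of 56 wild-type cells (51.8%, 38.03% to 65.3%) and in 36 of 37 Sox9Y440X/+ cells (97.3%, 85.8% to 99.9%). Over all cells the difference was 1.72, with mean FPKM of 4.34 and 15.03. FPKM per gene does not separate the transcripts of the 2 alleles, so this level does not check the genotype labels.

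Within epithelium-like cells, Sox10 and the otic gene Oc90 were lower in Sox9Y440X/+. Sox10 (ENSMUSG00000033006.9, chromosome 15, 79154908 to 79165240) was detected in 26 of 56 wild-type cells (46.4%, 32.99% to 60.3%) and in 2 of 37 Sox9Y440X/+ cells (5.41%, 0.661% to 18.2%). Its difference was -1.86, with mean FPKM of 15.6 and 1.46, and a single cell held 77.9% of the Sox9Y440X/+ total. Within cluster 3, Sox10 was detected in 11 of 11 wild-type and 1 of 11 Sox9Y440X/+ cells (-4.08), and within cluster 6 in 11 of 22 and 0 of 6 (-2.23). In cluster 1 it was detected in 1 of 8 and 0 of 5 cells, and in cluster 7 in 0 cells of either genotype. Oc90 (ENSMUSG00000015001.17, chromosome 15, 65876053 to 65912397), which encodes otoconin 90, an otoconial matrix protein, had the largest difference of all named genes, -7.02. It was detected in 53 of 56 wild-type cells (94.6%, 85.1% to 98.9%) and in 12 of 37 Sox9Y440X/+ cells (32.4%, 18.01% to 49.8%), with mean FPKM of 1490 and 102. Sox8 was not detected in any cell of either genotype. The otic and endolymphatic identity list, which includes Oc90, had a median of 0.04, at percentile 33.2, inside the range of random lists, with 8 of 13 detected members higher, among them Dlx6 (0.94) and Dach1 (0.61), and 5 lower, Oc90 and Spp1 (-1.88) among them. The mean FPKM of Dlx6 went the other way, 15.4 in wild type and 10.7 in Sox9Y440X/+, with 59.3% of the wild-type total in 1 cell.

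**Figure D2:**
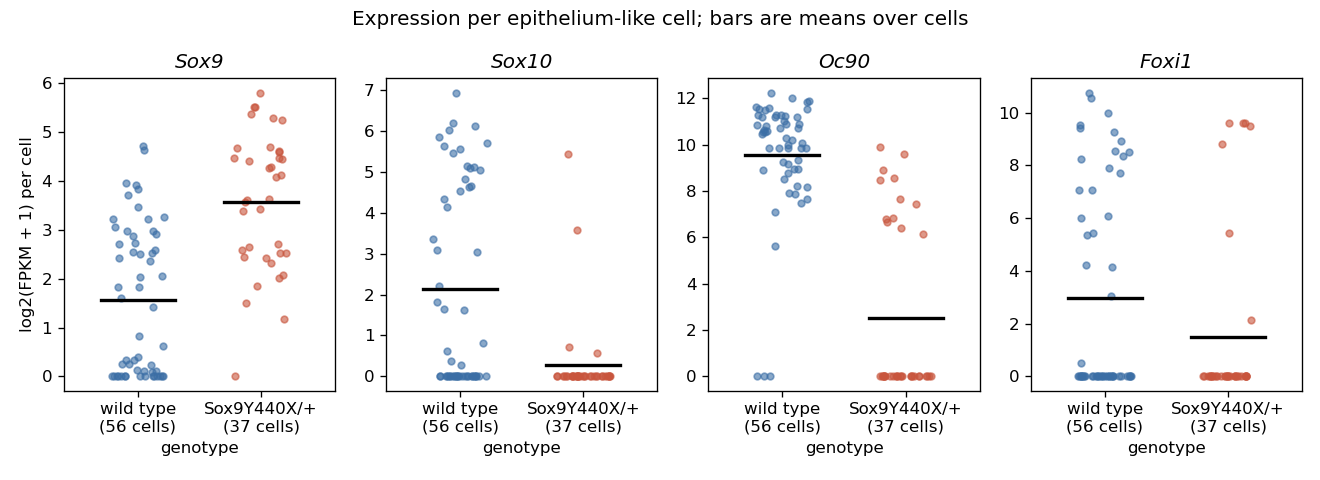
Expression of Sox9, Sox10, Oc90 and Foxi1 as log2(FPKM + 1) (y axis) in each of 56 wild-type and 37 Sox9Y440X/+ epithelium-like cells (x axis, genotype), with bars at the mean over cells. Sox9 was higher in Sox9Y440X/+ cells while Sox10 and Oc90 were detected in 2 and 12 of them.

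Genes of the ionocyte acid-base and anion transport list were lower in Sox9Y440X/+ epithelium-like cells. All 16 members detected in at least 10% of cells had lower means, and the median over 19 measured members was -0.58, at percentile 0.0 of random lists, whose central 95% reached from -0.003 to 0.37. Many of these genes were detected together in the same few cells, a pattern that random lists do not copy. Foxi1, the transcription factor that directs ionocyte identity, was at -1.50, and at -0.80 in cells with 2500 to 5500 genes, and was detected in 22 of 56 wild-type (39.3%, 26.5% to 53.2%) and 7 of 37 Sox9Y440X/+ cells (18.9%, 7.96% to 35.2%). Slc26a4, the anion exchanger pendrin, was at -1.47 and was detected in 12 (21.4%) and 2 (5.41%) cells, 1 of which held 77.2% of the Sox9Y440X/+ total. Car2, a carbonic anhydrase, was at -1.29, and Hepacam2 at -1.07 with detection in 8 wild-type and 0 Sox9Y440X/+ cells, which allows up to 9.49%. The list median was -0.27 in even-numbered and -0.94 in odd-numbered cells, -0.36 in cells with 2500 to 5500 genes and -0.33 outside the ionocyte-like cluster. Outside that cluster, 4 of 48 wild-type and 0 of 32 Sox9Y440X/+ cells still had at least 5 of the 19 list genes, so the -0.33 does not describe cells free of this type. Of all epithelium-like cells with at least 5 list genes, the 12 wild-type cells had 6 to 16 of them and the 5 Sox9Y440X/+ cells 7 to 12, and Slc26a4 was detected in 11 and 2 of these cells. Foxi1 was not lower in them, with a mean log2(FPKM + 1) of 9.04 in the wild-type and 9.43 in the Sox9Y440X/+ cells. However, Foxi1 is itself one of the list genes that picked these cells. The widely expressed V-ATPase subunits went both ways, with a median of -0.00, at percentile 3.49 and inside the range of random lists, 8 of 16 higher and 8 lower. The higher ones were led by Atp6v0e (1.20) and Atp6v1f (1.06), and the lower ones by Atp6ap1 (-0.90). Mean FPKM in wild type and Sox9Y440X/+ was close for Atp6v0e, at 288 and 299, and for Atp6v1f, at 228 and 248. Atp6v0e was detected in 60.7% and 81.1% of these cells and Atp6v1f in 76.8% and 89.2%. Atp6v1f turned sign against wild-type cells without Xist.

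Other genes lower in Sox9Y440X/+ epithelium-like cells by the fixed rule were Prss56 (-3.28), Agt (-3.26), which encodes angiotensinogen, Gfra1 (-2.48), Dkk3 (-2.45), Bricd5 (-2.41), Irgm1 (-2.12), Mme (-2.05), Cited4 (-2.04) and Gpx2 (-2.001, detected in 16 wild-type and 0 Sox9Y440X/+ cells). Tsix, antisense to Xist, was at -2.17 but at -0.04 when wild-type cells with Xist were left out. Genes higher were Cyr61 (3.46), a secreted matrix-associated protein, Cldn6 (2.86), Dusp1 (2.78), a stress-induced phosphatase, Calcoco1 (2.77), Vgll4 (2.71), Oxct1 (2.67), Errfi1 (2.63), Mospd2 (2.53), Hbegf (2.52), an EGF family ligand, Etfa (2.52), Wdr61 (2.46) and Ddah2 (2.46). Cldn6 is one of the markers that name the epithelium-like class. Cldn6, Vgll4 and Mospd2 were also among the 10 leading genes of cluster 2, which held 1 wild-type and 10 Sox9Y440X/+ cells. These 3 genes were not compared within clusters. Xist, a transcript of female cells, was detected in 34 of the 56 wild-type and 0 of the 37 Sox9Y440X/+ epithelium-like cells. Against the 22 wild-type cells without Xist, Dusp1 was at 1.57, Etfa at 1.33, Irgm1 at -1.18 and Spp1 at -3.55. Sox9Y440X/+ cells showed more detected genes. Of 5957 genes detected in at least 25% of the cells of a genotype, 72.8% had a difference above 0. Counts of higher or lower list members are to be read against that share. Over the 5957 genes the median difference was 0.36, so on this scale a list near 0 lies below the general level. That median was 0.21 in cells with 2500 to 5500 genes, 0.20 in even-numbered cells, 0.12 at a pseudocount of 10 and 0.07 as the log2 ratio of mean FPKM.

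Markers of cell types also differed within epithelium-like cells. The epithelium markers, which name the class, had a median of 0.86 at percentile 99.8. Of them 10 of 14 were higher, including Krt8 (1.53) and Cldn7 (1.36), and Spint2 (-0.97) and Elf3 (-0.51) were among the lower. That count is near the general share of genes above 0, 72.8%. The chondrocyte markers were at -0.06 and percentile 0.46, with 6 of 7 detected members lower.

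Among the programme lists in epithelium-like cells, p53 targets had a median of 0.51 at percentile 98.4, above the random lists, with 6 of 8 detected members higher, including Bax (1.24) and Cdkn1a (1.20). Bax was at -0.08 in even-numbered cells. Immediate-early and dissociation genes were inside the range, at 0.67 and percentile 95.7, with 10 of 15 higher, led by Dusp1 (2.78) and Ier3 (1.46). Epithelial junction genes were also inside it, at 0.39 and percentile 94.6, with 17 of 21 higher, led by Cldn6 (2.86), Ocln (2.04) and Cldn23 (1.53). The unfolded protein and integrated stress response list lay below the random lists, at -0.18 and percentile 0.175, with 9 of 13 lower, such as Pdia6 (-0.79) and Pdia4 (-0.76), beside Asns (1.63) and Hspa5 (0.79). Cartilage-type SOX9 target genes were at -0.06, percentile 0.56, with 7 of 10 lower, such as Lect1 (-1.63) and Col9a3 (-1.28), and at 0.03 in odd-numbered cells. All 11 chondrocyte markers are among the 16 members of this list, so the values of these 2 lists are not separate results. Proliferation genes were at -0.08, percentile 0.61, with 7 of 13 lower, such as Mcm2 (-1.21) and Cdk1 (-0.86). Cdk1 turned sign in odd-numbered cells. Glycolysis and hypoxia genes were at -0.08, percentile 1.08, with 8 of 14 lower, Slc2a1 (1.42) being higher. Against wild-type cells without Xist the proliferation median was 0.02, and in odd-numbered cells the glycolysis and hypoxia median was 0.10.

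**Figure D3:**
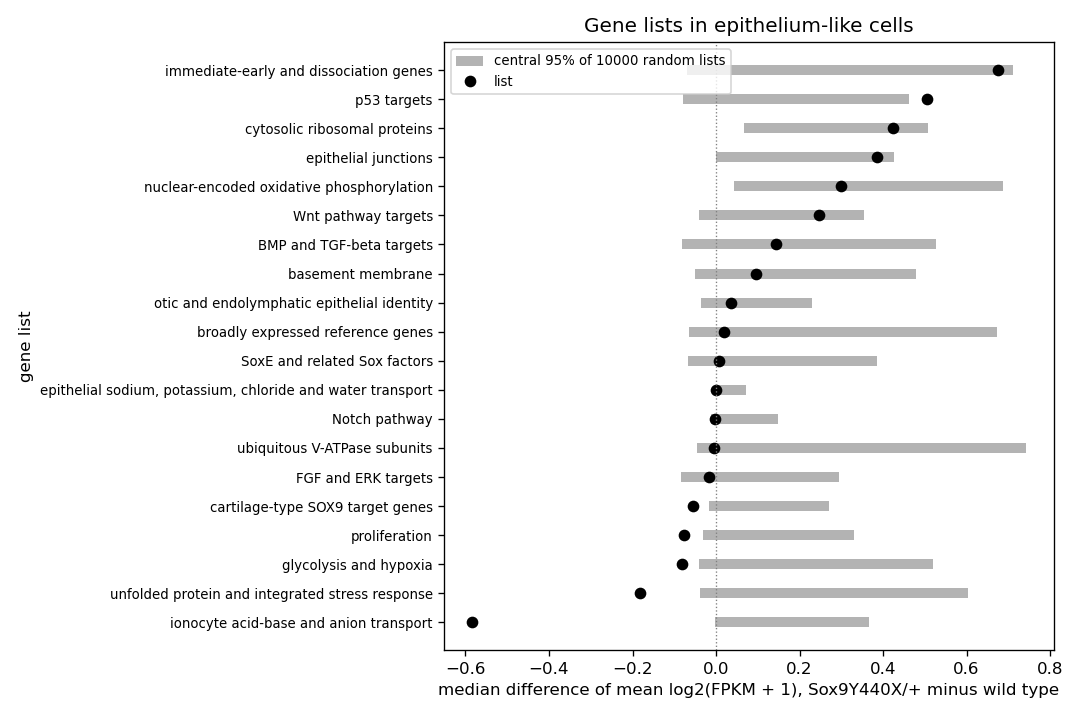
Median difference of mean log2(FPKM + 1) per gene list (x axis, Sox9Y440X/+ minus wild type; lists on the y axis) in epithelium-like cells, with grey bars for the central 95% of 10000 random lists of the same size. The ionocyte list lay farthest below its random lists, at -0.58.

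Further lists with medians inside the random range were the SoxE and related Sox factors (0.01, percentile 52.045, Sox9 2.01 and Sox10 -1.86), ion, chloride and water transport (0.00, percentile 41.1, Atp1b1 -1.35 and Kcnk1 1.13), basement membrane (0.10, percentile 24.8), and the Notch pathway (-0.00, percentile 5.69), in which Hes1 was at 2.38. Also inside it were Wnt pathway targets (0.25, percentile 90.4), BMP and TGF-beta targets (0.14, percentile 54.1, Id2 2.14 and Tgfbi -1.19), and FGF and ERK targets (-0.02, percentile 9.35). Nuclear-encoded oxidative phosphorylation (0.30, percentile 29.8), cytosolic ribosomal proteins (0.42, percentile 75.5, 22 of 24 higher) and broadly expressed reference genes (0.02, percentile 7.09) lay inside it as well. Of the genes named here, Kcnk1 turned sign in even-numbered cells.

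Over all cells the differences also carried the different mix of cell types. Lower genes were Oc90 (-7.77), Spint2 (-3.92), Prss56 (-3.91), Agt (-3.59), Spp1 (-3.44), Plekhb1 (-3.35), Fxyd3 (-3.34), Ptgds (-3.34), Gfra1 (-3.12), Epcam (-3.04), AU021092 (-3.04) and Wfdc2 (-2.64), of which Epcam and Spint2 are epithelium markers. Higher genes were Igfbp2 (3.62), Lgals1 (3.57), Ccnd2 (3.46), Cyr61 (3.46), Ddah2 (3.21), Stmn1 (3.18), Igfbp4 (3.08), Col1a2 (3.02), Crym (2.92), H2afv (2.72), Hist1h2ao (2.71) and Fstl1 (2.67). In wild type, 1 cell held 72.8% of the Col1a2 and 1 held 88.6% of the Crym total. The proliferation list had a median of 0.54, percentile 99.9, over all cells, with 22 of 24 members higher, in contrast to its value in epithelium-like cells. The ionocyte list was at -0.84, percentile 0.0, with 16 of 16 detected members lower. Also below the random lists over all cells were the unfolded protein and integrated stress response (-0.58, percentile 0.02, 10 of 13 lower), V-ATPase subunits (-0.48, percentile 0.37, 13 of 16 lower), glycolysis and hypoxia (-0.23, percentile 0.44, 10 of 14 lower), otic and endolymphatic identity (-0.12, percentile 0.1, 10 of 17 lower) and ion, chloride and water transport (-0.0053, percentile 0.22, 10 of 15 lower). The epithelium markers were at -1.19, percentile 0.0, and the mesenchyme markers at 0.63, percentile 100.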

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

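Of the 5 cells below 1000 genes, which the main comparisons leave out, 2 carried strong blood-cell transcripts. The Sox9Y440X/+ cell numbered 002c had 6 of 9 erythroid markers at an FPKM of at least 1, and the wild-type cell numbered 056 had 8. Hba-a1 reached an FPKM of 211743 in the first and 273807 in the second, whereas the highest value among the wild-type cells kept was 1.80. The embryonic globin Hbb-y was at 511719 in the wild-type cell and listed at 0 in the Sox9Y440X/+ cell. No explanation for these cells was tested.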

How the results depend on the processing

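Wild-type cells without Xist, cells outside the ionocyte-like cluster, and the factor of 1.5 that counts as a move for a difference or median were chosen after seeing the data. No paired analysis was possible because the cell numbers are names only and no test was made. Of 128 gene differences of at least 1 log2 unit, 969 of 1268 recomputed values stayed within a factor of 1.5, 291 moved further and 8 turned sign. Part of this tally was fixed in advance. Genes named for the largest differences had to keep their sign in odd-numbered cells, in even-numbered cells and after scaling to the same total. In epithelium-like cells the setting of all 120 cells held the same 56 wild-type and 37 Sox9Y440X/+ cells as the main comparison. Class shares were the same under 5 or 12 clusters and 3000 variable genes and moved within their intervals for cells with at least 2000 genes.

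The Sox9 difference kept its direction throughout but followed the pseudocount, which compresses low values by construction: 2.74 over all cells and 3.20 in epithelium-like cells at a pseudocount of 0.1, and 0.70 and 0.81 at 10. Sox10 in epithelium-like cells followed it too, at -3.20 and -0.76, as did Oc90, at -9.09 and -4.95. As the log2 ratio of mean FPKM the Oc90 difference in these cells was -3.86. The share of cells with Sox9 followed its limit. For FPKM above 0 it was 73.7% of all wild-type and 73.2% of wild-type epithelium-like cells. In Sox9Y440X/+ epithelium-like cells it stayed at 97.3%, the share at an FPKM of at least 1. For an FPKM of at least 10 it was 14.04% and 12.5% in wild type and 56.9% and 56.8% in Sox9Y440X/+. Among the 2000 highest genes of a cell it was 15.8% and 16.1% in wild type and 27.6% and 32.4% in Sox9Y440X/+.

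The ionocyte median in epithelium-like cells stayed below 0: -0.96 and -0.35 at pseudocounts of 0.1 and 10, -1.64 as the log2 ratio of mean FPKM, -0.36 in cells with 2500 to 5500 genes, -0.94 in odd-numbered and -0.27 in even-numbered cells, -1.26 against wild-type cells without Xist and -0.33 outside the ionocyte-like cluster, where 4 of 48 wild-type and 0 of 32 Sox9Y440X/+ cells still had at least 5 ionocyte genes.

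Among differences of at least 1 log2 unit and lists outside the random range, the values that turned sign, with the cause not tested, were over all cells Krt18 (0.22) and Krt8 (0.42) as the log2 ratio of mean FPKM, and in odd-numbered cells Btg2 (0.066) and the glycolysis and hypoxia list (0.061). In epithelium-like cells they were Col1a2 (-0.065), Kcnk1 (-0.046) and Bax (-0.077) in even-numbered cells, Atp6v1f (-0.14), Atp5c1 (-0.043) and the proliferation list (0.023) against wild-type cells without Xist, the cartilage-type SOX9 target list (0.034) in odd-numbered cells, and the glycolysis and hypoxia list in odd-numbered cells (0.10) and outside the ionocyte-like cluster (0.068). Smaller differences and lists inside the range turned sign as well, such as Dlx6 (-0.50) and the immediate-early list (-0.15) as the log2 ratio of mean FPKM, Cdk1 (0.051) in odd-numbered cells and oxidative phosphorylation (-0.31) against wild-type cells without Xist. Unknown depth limits all shares of cells, and Sox9Y440X/+ cells had more detected genes.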

Other observations

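All tests of explanations in this part were chosen after the results were seen, although cells with 2500 to 5500 genes were a setting fixed before the data were examined. The mesenchyme-like class can also be named by chondrocyte markers. Their mean level lay near that of mesenchyme markers, at 2.75 against 2.99 in cluster 4 and 1.87 against 1.97 in cluster 5. The mesenchyme-like cells of the Sox9Y440X/+ sample expressed cartilage-type genes as well as mesenchyme collagens. Col2a1 was detected in 19 of 21 of them (90.5%, 69.6% to 98.8%) at a mean FPKM of 179, and Col9a1 in 18 of 21 at 165, while Matn1 was detected in 0 and Acan in 3, with 80.8% of the Acan total in 1 cell. Sox9 was detected in 17 of 21 (81.0%, 58.1% to 94.6%) at a mean FPKM of 12.3. Pou3f4 and Tbx18, transcription factors of otic mesenchyme, were detected in 0 of 21, which allows up to 16.1%, whereas the 1 wild-type mesenchyme-like cell had Pou3f4 and Acan. The division genes Mki67 and Top2a were detected in 10 and 9 of them.

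Xist, expressed from the inactive X chromosome of female cells, reached an FPKM of 1 in 35 of 57 wild-type cells and in 0 of 58 Sox9Y440X/+ cells. A Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) was detected in 10 wild-type and 34 Sox9Y440X/+ cells, and no cell had both. The wild-type cells therefore came from embryos of both sexes, and no Sox9Y440X/+ cell showed Xist. Neither Xist nor a Y-linked gene was detected in 24 Sox9Y440X/+ and 12 wild-type cells. Wild-type cells without Xist were therefore not all shown to be male. Within 10 Mb of Sox9, 0 of 102 genes in epithelium-like cells differed by at least 2 log2 units from the median of all genes, against 48 of 5855 elsewhere (0.82%). At the share seen elsewhere very few of 102 genes would do so, and Sox9 itself, at 2.01, misses this limit with the median at 0.36. These counts therefore do not decide whether linked genes differed.

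Oc90 was lower in Sox9Y440X/+ epithelium-like cells, with a difference of -7.02, or -3.86 as the log2 ratio of mean FPKM. Sex alone is argued against, as far as wild-type cells without Xist are male, by a difference of -6.94 against these cells. The number of detected genes is argued against by -7.64 in cells with 2500 to 5500 genes. Another mix of epithelial clusters is argued against by the value nearest 0 within a cluster of at least 4 cells of each genotype, -4.78. No biological explanation was tested, and animal, litter, exact stage and dissection cannot be told apart from genotype with 1 sample each.

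Ionocyte genes were lower in Sox9Y440X/+ epithelium-like cells. Sex as the whole cause is argued against, as far as wild-type cells without Xist are male, by a list median of -1.26 against these cells. Against all wild-type epithelium-like cells it was -0.58. The wild-type cells with and without Xist thus differed in these genes, and the size of the result depends on which of them are compared. In cells with 2500 to 5500 genes the list median was -0.36, below the random lists. Random lists do not copy genes detected together in the same few cells, so this place does not decide on the number of detected genes. Sox9Y440X/+ epithelium-like cells had more detected genes, a median of 3959 against 2822.5 in wild type, while the ionocyte genes were lower in them. Fewer ionocyte-like cells in the Sox9Y440X/+ sample cannot be told apart from fewer ionocyte genes in each such cell. Among epithelium-like cells with at least 5 ionocyte genes, the median number of them was 8 in 5 Sox9Y440X/+ and 14 in 12 wild-type cells, a difference of -6, but the ranges, 7 to 12 and 6 to 16, overlapped, the cells are few and they were picked by the genes counted. Mean Foxi1 was not lower in the Sox9Y440X/+ ones, at 9.43 against 9.04 log2(FPKM + 1), although Foxi1 is itself one of the genes that picked them. Such cells made up 13.5% (4.54% to 28.8%) of Sox9Y440X/+ and 21.4% (11.6% to 34.4%) of wild-type epithelium-like cells. Animal, litter, stage and dissection stay open too.

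Mesenchyme-like cells were almost confined to the Sox9Y440X/+ sample. Doublets of an epithelial and a mesenchymal cell are argued against as their source. Of the 58 Sox9Y440X/+ cells used, 0 had at least 5 epithelium and at least 5 mesenchyme markers. The median of 0 epithelium markers in mesenchyme-like cells is partly set by the rule that names them. More tissue around the sac in the mutant dissection could give the same shares, and with 1 mesenchyme-like cell in the wild-type sample and 1 sample per genotype it cannot be told apart from an effect of the allele.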
